A study of Homo sapiens with 10 samples.

How the data were processed

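The data were gene expression measurements on Illumina beadchips from Meg01, a human megakaryoblastic leukaemia cell line. Per the labels' protocols, cells were grown in medium with 10% fetal calf serum and transduced with lentivirus at a multiplicity of infection of 10. The virus carried either a short hairpin against ATXN2, named sh95, or a control hairpin, named shc002. GFP-positive cells were sorted 48 hours later, and the sorted cells were lysed and spun through 7% to 46% sucrose, which separates mRNAs by the number of ribosomes they carry. RNA of gradient fractions 1 to 8 was pooled as subpolysomal and that of fractions 9 to 17 as polysomal, and biotin-labelled cRNA was made from each pool. The sources differ on the polysomal pool, since the series text counts 8 fractions in it and 9 to 17 make 9. The labels describe 3 independent experiments.

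The 10 arrays fell into 4 groups by hairpin and pool. There were 2 control and 2 knockdown arrays of subpolysomal RNA, numbered P1 and P3, and 3 control and 3 knockdown arrays of polysomal RNA, numbered P2, P4 and P5. Within a pool a control and a knockdown array share each P number, while no number occurs in both pools. Which P number belongs to which of the 3 experiments is not given in the sources used here.

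The values used were the processed probe intensities deposited by the authors, 47323 probes for each array. These deposited intensity values are on a linear scale with a minimum of 155.4, and their array medians lay between 193 and 194. The authors' normalization and background correction are not given in the sources used here, and the submitters' processing notes name R 2.15. That the scale is linear and that no gene was centred was read from the values themselves. A second table with unnormalized signals holds 20 columns, 10 of signal and 10 of detection p-values, whose headings match no sample label. Those columns were not used here. The plan had been to correct and normalize such scanner signals with neqc, so starting from the authors' intensities departs from it, and the 2 other background corrections of that plan (none, and normexp with an offset) had nothing to act on.

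The deposited intensities were log2-transformed and quantile-normalized over the 10 arrays. This gives every array the same distribution, so a difference between pools or hairpins is relative to the other probes. It gives no share of an mRNA on polysomes and cannot show a shift of all mRNAs together. The background of each array was modelled by mirroring its log2 values below their mode, and a probe counted as above background where it exceeded the 0.05 upper tail of that distribution. The mode lay between 186.8 and 187.7 intensity units, and 18365 to 20673 probes per array were above background. Probes above background on at least 2 arrays were kept, which left 26823 probes, 56.7% of the table. The number of arrays limits the precision of all comparisons.

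Gene names came from the platform annotation, with symbols updated by gene identifier to a RefSeq gene table of the GRCh38.p14 assembly, which held 30074 of the named probes. One gene symbol was found for 30113 probes, several for 8 and none for 17202. Among the kept probes 18619 had 1 symbol, for 13879 genes. Each gene was represented by its kept probe with the highest mean, and disagreement with other probes of the gene is given beside the value. No probe position is printed, since no genome build is named for the array.

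A single limma model of 4 group means was fitted to all 10 arrays (lmFit and eBayes, limma 3.58.1, R 4.3.3), so that the groups share an estimate of the spread. Probes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 6 comparisons were knockdown against control in polysomal RNA, in subpolysomal RNA and averaged over both, polysomal against subpolysomal RNA in control and in knockdown cells, and the change of that ratio with knockdown. All adjusted p-values of genes come from this limma fit unless another is named. Values are log2 differences with their standard error (SE).

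Groups of genes were tested with camera from limma on 1 probe per gene with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. fry asks whether a list's genes moved on balance one way and does not compare them with other genes. The 25 lists hold 821 genes, of which 756 were on the array and 698 were measured. They covered ribosomal proteins, translation factors, ATXN2 partners with P-body and stress granule components, megakaryocyte and platelet genes, erythroid genes, monocyte and granulocyte markers, lymphoid markers, mast cell and basophil markers, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the proteasome, endoplasmic reticulum stress, ATF4 targets and amino acid response, heat shock and chaperonin genes, interferon response, S phase genes, G2 and M phase genes, p53 targets, cholesterol synthesis, glycolysis, short-lived immediate early and AU-rich mRNAs, replication-dependent histones, nuclear and small nucleolar host noncoding RNAs, mRNAs with known upstream reading frame or iron or polyamine control, and the autophagy, lysosome and mTOR pathway. The mitochondrially encoded list had no measured member, which left 24 lists to test. Lists, comparisons, the model and most other settings were fixed before the data were examined.

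ATXN2 was reported first. For each comparison the text then names up to 10 genes with the largest change in each direction among those past the threshold whose arrays do not overlap between the groups. Where fewer than 3 genes passed in a direction, it names the 5 with the smallest p, as values that did not pass. From each list that passed or held a passing member, it names up to 4 members with the smallest p. Genes known only by a clone name were skipped.

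Whether P numbers pair the arrays was checked from the correlation, across probes, of array deviations from their group means. It was 0.917 for P1, 0.917 for P3, 0.763 for P2, 0.769 for P4 and 0.467 for P5, all above the limit of 0.1, so the numbers were taken to pair the arrays of a pool. Control P5 with knockdown P4, which share no number, also lay above the limit, at 0.272. Their levels correlated at 0.950, against 0.954 for the P5 pair. The limit alone thus does not single out the pairs, and P5 is the least certain. All other unmatched arrays of a pool had negative values. The 0.917 follows in part from having 2 arrays per group. Fits with the P number as a replicate block are given where they change a call. No 2 arrays held identical values. Arrays of a group correlated at 0.819 to 0.951 and arrays of the same P number in a pool at 0.938 to 0.993.

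As a check of RNA quality, the difference between the 2 brightest probes of a gene was taken for 694 genes with at least 2 probes of mean log2 8.5 or more. The first principal component of these differences, named the probe-difference axis, held 72.4% of their variance. Probes of one gene report the same gene, so this axis follows signal that depends on the probe. This axis, like the fits that use it, was chosen after seeing the data.

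The statistics were tested on simulated data with 200 of 26823 probes changed, in 5 runs per comparison. For knockdown against control in polysomal RNA, 59.6% of probes changed by 1 log2 unit and 79.8% of those changed by 2 were recovered, and with the replicate block 69% and 89.6%. For subpolysomal RNA the shares were 53.6% and 74.4%, and 62.2% and 86% with the block. For polysomal against subpolysomal RNA in control cells they were 58.2% and 74.2%, and for the change of that ratio 48.2% and 66.2%. Mean false calls per run lay between 6.2 and 9.4. The changed probes were drawn at random from all kept probes, of which 10522 were above background on every array. Each received the full change, while real changes near background are compressed. The shares can thus overstate the recovery of real changes, and a count of 0 calls does not show that such changes were absent. In the runs without the block the simulated spread was independent between arrays, which the real arrays were not. The runs with the block added a shift shared by arrays of a P number. Both kinds of run thus used different data, and the fit without a block was not tried on paired data. camera called 100% of simulated lists shifted by 0.5 and 0 of 950 unshifted lists. The simulated genes were independent of one another, so this check cannot show how the preset correlation fares where genes move together. On the real data, other splits of the polysomal arrays gave up to 10 lists.

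Alternatives covered the normalization, the filter, the model, the threshold, the replicate block and leaving out each array, and their effect is given in the closing section. Single values were compared by exact permutation tests, two-sided. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.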

Results

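ATXN2, the target of the hairpin and an RNA-binding protein found with poly(A)-binding protein on mRNAs, was lower on every knockdown array than on its control partner. In subpolysomal RNA the control arrays read log2 9.31 (P1) and 9.87 (P3) and the knockdown arrays 8.99 and 8.67. In polysomal RNA the control arrays read 9.18 (P2), 10.77 (P4) and 9.67 (P5), and the knockdown arrays 8.68, 8.69 and 8.64. The control arrays spread more widely (SD 0.40 in subpolysomal and 0.82 in polysomal RNA) than the knockdown arrays (SD 0.22 and 0.03). Averaged over both RNA pools the difference was -0.99 (SE 0.30, 95% confidence interval -1.70 to -0.27), 50.5% of control (n = 5 against 5 arrays), with an exact p of 0.0167, the smallest possible with 120 relabellings. It was -1.21 (SE 0.38), 43.3% of control, in polysomal RNA (n = 3 against 3, exact p 0.1, the smallest possible) and -0.76 (SE 0.47), 58.9% of control, in subpolysomal RNA (n = 2 against 2, exact p 0.333, the smallest possible). The paired differences were -0.32, -0.50, -1.20, -2.09 and -1.04 for P1 to P5, with a mean of -1.03 and a paired exact p of 0.0625, the smallest possible. The exact p of 0.0167 relabels single arrays within each pool and ignores the P numbers, although arrays of a number deviate together. The paired exact p of 0.0625 counts the 5 P numbers as independent. With 3 experiments described some subpolysomal and polysomal arrays may share an experiment, so both p-values can be too small. Among all probes tested by limma the adjusted p was 1.0 for each of these differences. Without control array P4 the polysomal difference was -0.77, and without control array P3 the subpolysomal difference was -0.49. The levels matched the hairpin labels of all 10 arrays.

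**Figure D1:**
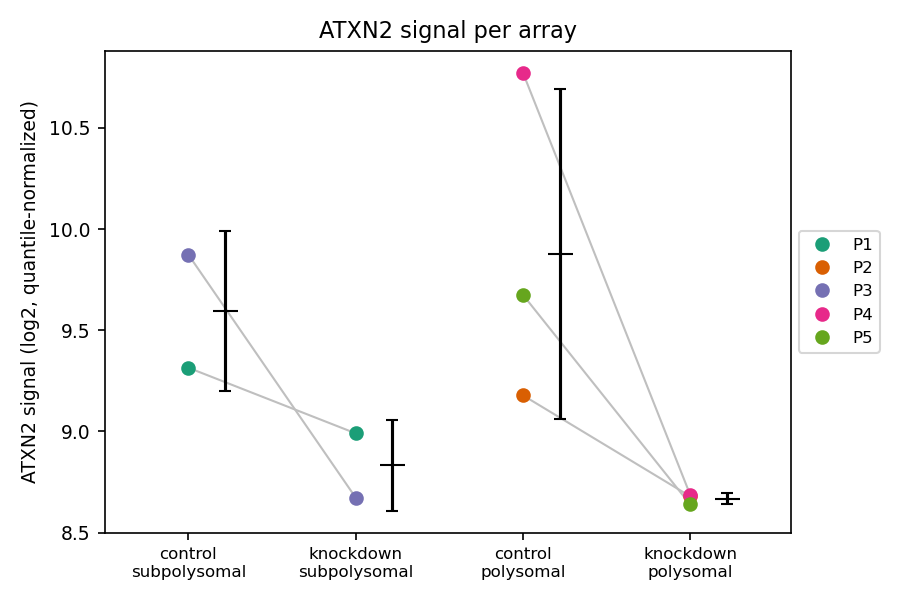
ATXN2 signal (vertical axis, log2 of quantile-normalized intensity) for each array in the 4 groups, where points are arrays coloured by P number, grey lines join arrays of the same number and black bars give mean and SD. Knockdown means were 8.83 in subpolysomal and 8.67 in polysomal RNA, against 9.59 and 9.88 in control cells.

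In polysomal RNA of ATXN2 knockdown cells (n = 3 against 3) no single gene passed the threshold, but 6 of 24 gene lists shifted as groups by camera. Replication-dependent histone mRNAs fell by a median of 0.12 (24 of 29 lower), ribosomal protein mRNAs by 0.26 (48 of 68 lower), nuclear-encoded oxidative phosphorylation mRNAs by 0.20 (50 of 70 lower) and cholesterol synthesis mRNAs by 0.18 (16 of 20 lower). Targets of ATF4, the transcription factor of the amino acid response, rose by 0.39 (25 of 28 higher) and translation factors by 0.15 (32 of 47 higher). None of these shifts held with a correlation estimated from the arrays, where the adjusted p was 0.20 for translation factors and 0.67 for each of the other lists. limma called 0 of 26823 probes, with 422 at an unadjusted p under 0.05 where 1341 would be expected by chance. This fit leaves the differences between pairs in its error, so the 422 do not show fewer changes than chance. With the replicate block limma also called 0, with 1656 at that unadjusted level.

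Among the genes with the smallest p, none of which passed, SRRT, which acts with the nuclear cap-binding complex, read 0.38 (SE 0.05) higher in polysomal RNA with knockdown. PFKP, a phosphofructokinase of glycolysis, read 0.90 (SE 0.13) higher, and DCAF7, AATF and CTTNBP2NL 0.45 (SE 0.09), 0.74 (SE 0.16) and 0.17 (SE 0.04). On the lower side NCK2, an adaptor of tyrosine kinase signalling, read -0.87 (SE 0.24), RPL11 -0.27 (SE 0.08), MRPS28, a protein of the mitochondrial ribosome, -0.76 (SE 0.24) and UBXN8 -0.15 (SE 0.05). OR2A1 was above background in control arrays only, at least 1.07-fold. The limma adjusted p was 1.0 for all of them.

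Within the lists that shifted in polysomal RNA, ribosomal protein genes pointed both ways, with RPS12 at -0.80 (SE 0.38), RPS27 at -1.27 (SE 0.61) and RPL7A at 0.90 (SE 0.50), and 0 of 68 passed when adjusted over the list alone. EIF4B, which aids the unwinding of mRNA leaders, read 0.76 (SE 0.25), EIF2B3 0.65 (SE 0.27), the ribosome recycling factor ABCE1 0.38 (SE 0.15) and EIF2B4 0.37 (SE 0.15). In oxidative phosphorylation NDUFA10 read 0.48 (SE 0.15), ATP5F1A 1.00 (SE 0.48) and ATP5PB 0.32 (SE 0.19), against the direction of the list (but ATP5PB -0.34 with median centring and -0.35 with the authors' values), and ATP5PF -0.83 (SE 0.57). The ATF4 list was led by the tryptophan tRNA synthetase WARS1 at 1.44 (SE 0.65), the asparagine synthetase ASNS at 1.40 (SE 1.00) and the amino acid transporter SLC7A5 at 0.81 (SE 0.56). Without the P1 and P2 arrays ASNS read 0.10 and SLC7A5 -0.03. For cholesterol synthesis HMGCS1 read -1.05 (SE 0.88), IDI1 -0.49 (SE 0.62), INSIG1 -0.43 (SE 0.30) and HSD17B7 -0.35 (SE 0.37). Among histones H2BC5 read -0.79 (SE 0.44), while H2AC11, H3C8 and H4C14, near the array floor, read -0.12, -0.10 and -0.06. Glycolysis, at a median of 0.08, had 1 member higher adjusted over the list alone, PFKP, and the other passing and non-passing lists had none. With the replicate block all 6 lists passed, with adjusted p of 1.3e-06 for histones, 1.4e-06 for ribosomal proteins, 0.0044 for oxidative phosphorylation, 0.0047 for cholesterol synthesis, 0.0049 for translation factors and 0.048 for ATF4 targets. In that fit none passed with an estimated correlation (adjusted p = 0.877 with an estimated correlation for ATF4 targets and 0.790 for each of the others). With median centring and with the authors' values translation factors no longer passed (0.05 and 0.04), while ribosomal proteins stood at -0.70 and -0.71 and oxidative phosphorylation at -0.57 and -0.58.

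**Figure D2:**
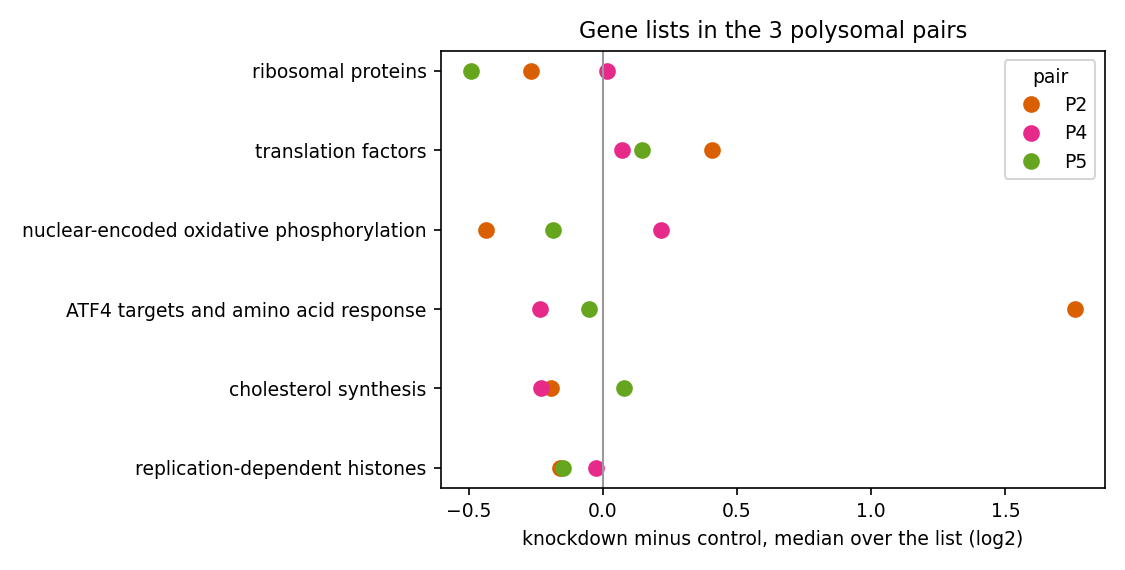
Median log2 difference between knockdown and control polysomal RNA (horizontal axis) for the 6 gene lists that shifted, where each point is 1 of the 3 array pairs coloured by P number. ATF4 targets read 1.76 in pair P2 against -0.23 in P4 and -0.05 in P5.

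The array pairs did not share most of these shifts. ATF4 targets stood at 1.76 in pair P2, where 28 of 28 genes were higher, and at -0.23 and -0.05 in P4 and P5. Ribosomal proteins stood at -0.27, 0.02 and -0.49 in P2, P4 and P5, oxidative phosphorylation at -0.44, 0.22 and -0.19, and cholesterol synthesis at -0.19, -0.23 and 0.08. Translation factors (0.41, 0.07 and 0.14) and histones (-0.16, -0.02 and -0.15) kept their direction in all 3. The control array of P2 differed from the others in the mRNA of the cytoskeletal actin ACTB, which read 8.36 to 8.84 on all 3 of its probes, and in its highest deposited intensity, 140375 against 11164 to 38625 on the other arrays. Pair P5 was far apart on the probe-difference axis, with knockdown minus control at -18.6 against -1.46 in P2 and 1.52 in P4. Without knockdown array P2 ribosomal proteins stood at 0.03, oxidative phosphorylation at -0.0034, ATF4 targets at 0.02, cholesterol synthesis at -0.00 and histones at -0.07, and none of these passed. Without control array P2 ATF4 targets (0.06) and translation factors (0.14) no longer passed, and ribosomal proteins stood at -0.56 and cholesterol synthesis at -0.31. Without control array P4 ribosomal proteins (-0.16) and cholesterol synthesis (0.09) no longer passed, with ATF4 targets at 0.81, oxidative phosphorylation at -0.32 and translation factors at 0.25. Without knockdown array P4 ATF4 targets (0.25) and translation factors (0.21) no longer passed, with ribosomal proteins at -0.43, cholesterol synthesis at -0.40, oxidative phosphorylation at -0.36 and histones at -0.07. Without control array P5 ribosomal proteins (-0.16), ATF4 targets (0.24), oxidative phosphorylation (-0.12) and histones (-0.08) no longer passed. Without knockdown array P5 cholesterol synthesis (-0.12) no longer passed and ATF4 targets stood at 0.78.

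Lineage and stress lists did not pass in polysomal RNA. Megakaryocyte and platelet genes stood at a median of 0.01 (20 of 38 higher), erythroid genes at -0.02, monocyte and granulocyte markers at 0.03, lymphoid markers at 0.01 and mast cell and basophil markers at -0.15. ATXN2 partners with P-body and stress granule components stood at 0.10 (16 of 26 higher), endoplasmic reticulum stress genes at 0.07, heat shock genes at 0.09, interferon response at 0.04 and p53 targets at -0.01. The proteasome stood at 0.13, S phase genes at -0.00, G2 and M phase genes at 0.03, immediate early and AU-rich mRNAs at -0.04, noncoding RNAs at -0.04, mRNAs with upstream reading frame or iron or polyamine control at -0.02, and autophagy, lysosome and mTOR genes at 0.08. With the replicate block the noncoding RNAs passed in polysomal RNA with an adjusted p of 0.048 (adjusted p = 0.790 with an estimated correlation in that fit).

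In subpolysomal RNA (n = 2 against 2) neither a gene nor a list passed with knockdown in the main fit. Some lists passed with median centring and with the authors' values, as counted in the closing section. Cholesterol synthesis mRNAs stood at -0.19 with 19 of 20 lower, at -0.40 in pair P3 and 0.07 in P1. Their adjusted p was 0.18, and 0.00019 with the replicate block (adjusted p = 0.89 with an estimated correlation in that fit). Erythroid genes stood at 0.08 (16 of 22 higher), noncoding RNAs at 0.09 (16 of 21 higher) and histones at 0.05 (23 of 29 higher), with adjusted p of 0.18, 0.18 and 0.19. The genes with the smallest p, none passing, were ZFYVE19 at -0.31 (SE 0.06), PGP, a phosphoglycolate phosphatase, at -0.29 (SE 0.06), YIPF1 at -0.47 (SE 0.12), FGFRL1 at -0.36 (SE 0.10) and, on the higher side, the spliceosomal RNA RNU6-1 at 0.67 (SE 0.17). BMP10, HLA-DQB1, GGA1 and RIMKLB were above background in knockdown arrays only (at least 1.04-, 1.06-, 1.02- and 1.06-fold), and PLVAP in control arrays only (at least 1.04-fold). limma called 0 probes, with 243 at an unadjusted p under 0.05, and 0 with 590 under the replicate block.

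Averaged over both pools (n = 5 against 5), 2 lists shifted with ATXN2 knockdown at the preset correlation and none with an estimated one. Cholesterol synthesis mRNAs fell by a median of 0.20 (adjusted p 0.0036, adjusted p = 0.75 with an estimated correlation). In the average 20 of 20 were lower, while by pair the list stood at 0.07 in P1, -0.19 in P2, -0.40 in P3, -0.23 in P4 and 0.08 in P5. HMGCS1, an early enzyme of the pathway, read -0.65 (SE 0.70), INSIG1, which retains the SREBP activating protein in the endoplasmic reticulum, -0.28 (SE 0.24) and TM7SF2 -0.24 (SE 0.22). Translation factors rose by 0.10 (32 of 47 higher, adjusted p 0.049, adjusted p = 0.32 with an estimated correlation), with EIF3H at 0.46, EIF4B at 0.44 and EIF4EBP2, a repressor of cap-dependent translation, at -0.18. With the replicate block both lists passed with adjusted p of 8.8e-07 and 0.024, and ribosomal proteins (-0.12, 0.0055) and histones (-0.02, 0.041) passed as well, but each of the 4 had adjusted p = 0.938 with an estimated correlation in that fit. Among single genes, none passing, SRRT read 0.22 (SE 0.04), PFKP 0.45 (SE 0.11), ARL14EPL 0.13, RAB14 0.13 and RIMKLB 0.11, and DPYSL2 read -0.22 (SE 0.05), YIPF1 -0.29 (SE 0.08), ZFYVE19 -0.18, PGP -0.17 and ABHD12B -0.10. limma called 0 probes, with 234 at an unadjusted p under 0.05, and 0 with 908 under the replicate block.

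The averaged cholesterol shift rested on few arrays. It no longer passed without control polysomal P4 (-0.03), control subpolysomal P3 (0.03), knockdown polysomal P2 (-0.08) or knockdown subpolysomal P1 (-0.09), and stood at -0.36 without control subpolysomal P1. For translation factors the call ended without control polysomal P2 (0.05), control subpolysomal P1 (0.07), knockdown polysomal P4 (0.13), knockdown polysomal P5 (0.09) or knockdown subpolysomal P3 (0.13), and the median was 0.06 without control polysomal P5 and 0.15 without control subpolysomal P3. The knockdown differences of all genes in the polysomal and the subpolysomal pool correlated at -0.106 over 26823 probes (rho -0.0943), and at -0.111 over the 10522 probes above background on every array. Of 30 relabellings 26 gave a correlation as large, the highest other 0.802, and of the 8 that part every pair 6 did, the highest other 0.252. Without control subpolysomal P1, control subpolysomal P3, knockdown subpolysomal P1 and knockdown subpolysomal P3 it was 0.378, -0.472, -0.489 and 0.341.

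Polysomal and subpolysomal RNA of control cells (n = 3 against 2) differed most firmly in noncoding transcripts on the lower side and in proteasome mRNAs on the higher side. Nuclear and small nucleolar host noncoding RNAs fell by a median of 1.15 in polysomal RNA (19 of 21 lower, adjusted p 9.1e-11, adjusted p = 0.0064 with an estimated correlation). Proteasome mRNAs rose by 0.70 (27 of 27 higher, adjusted p 2.9e-07, adjusted p = 0.026 with an estimated correlation). Both lists also passed by fry, with adjusted p of 0.00061 and 0.0040. limma called 34 probes, 3 higher and 31 lower, of which 10 have no gene name, and 15 with the replicate block. In the fit of group means the control and knockdown arrays of a P number count as independent, so its p-values can be too small. No P number occurs in both pools, so a difference between pools cannot be separated from differences between their P numbers. The list tests between pools were not run with a replicate block. No probe was called with only the arrays compared or with a trended and robust prior. With each pair averaged first, over both hairpins, 1 probe was called.

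Genes higher in polysomal RNA of control cells were SRRT, at 0.76 (SE 0.06, adjusted p 0.0187), the Wnt coreceptor LRP5, at 1.00 (SE 0.12, adjusted p 0.0479), and CCDC32, at 0.99 (SE 0.09, adjusted p 0.0313). SRRT read 9.84 in subpolysomal and 10.60 in polysomal control RNA. Of 20 named genes that were lower, the farthest called on the brightest probe of the gene were NME4, a mitochondrial nucleoside diphosphate kinase, at -2.83 (SE 0.34), the selenoprotein SELENOW at -2.15 (SE 0.25), the Groucho family corepressor TLE5 at -2.07 (SE 0.20), the long noncoding OIP5-AS1 at -1.93 (SE 0.21) and the lysosomal iduronate sulfatase IDS at -1.88 (SE 0.22). They were followed by FAAP20 of the Fanconi anaemia core complex at -1.68 (SE 0.12), the amidohydrolase NTAN1 at -1.54 (SE 0.16), RNF11 at -1.38 (SE 0.15), ZNF358 at -1.37 (SE 0.14) and FAM219B at -1.21 (SE 0.10). Adjusted p for these ran from 0.0168 for FAAP20 to 0.05 for IDS. Second, dimmer probes of LRP5, CCDC32, TLE5 and FAAP20 did not pass, 2 of 3 IDS probes did, and the RPS29 call rested on 1 of 4 probes (-2.38, the others -0.19 to -0.38). CNOT7, a deadenylase, was called on 1 of 3 probes (-1.35), not its brightest.

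Among the noncoding RNAs of control cells the small nucleolar host genes EPB41L4A-AS1 and SNHG5 read -2.48 (SE 0.38) and -2.09 (SE 0.56) and the imprinted MEG3 -0.43, with 5 of 21 lower when adjusted over the list alone. Proteasome subunits PSMB6, PSMB1, PSMA3 and PSMA6 read 1.85 (SE 0.29), 1.15 (SE 0.33), 0.96 and 0.61 (SE 0.19), with 1 higher adjusted over the list alone. Ribosomal protein mRNAs fell by a median of 0.37 (46 of 68 lower, adjusted p 0.00052, adjusted p = 0.46 with an estimated correlation), with RPL23A at -1.81 (SE 0.45), RPL13 at -1.68 (SE 0.38) and RPLP2 the other way at 0.36 (SE 0.09), and 1 lower adjusted over the list alone. Their median was -0.69 with median centring, -0.75 with cyclic loess and -0.69 with the authors' values, with 54 of 68 lower in each. Oxidative phosphorylation mRNAs rose by 0.47 (53 of 70 higher, adjusted p 0.00031, adjusted p = 0.46 with an estimated correlation), with SDHA at 1.49 (SE 0.53), COX6C at 1.06 (SE 0.30), ATP5F1B at 1.00 (SE 0.17) and NDUFB8 at 0.90 (SE 0.21), and 1 higher adjusted over the list alone.

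Proliferation lists were also higher in polysomal RNA of control cells, S phase genes by 0.26 (27 of 31 higher, adjusted p 0.0056) and G2 and M phase genes by 0.31 (37 of 48 higher, adjusted p 0.017), each with adjusted p = 0.46 with an estimated correlation. The flap endonuclease FEN1 read 1.92 (SE 0.73), the methylation maintenance factor UHRF1 1.04 (SE 0.41), CDK1 0.95 (SE 0.43) and CCNB2 0.67 (SE 0.36). Erythroid genes rose by 0.23 (18 of 22 higher, adjusted p 0.013, adjusted p = 0.46 with an estimated correlation), with the embryonic globin HBE1 at 1.63 (SE 0.60), CA2 at 0.89 (SE 0.44) and the fetal globins HBG1 and HBG2 at 0.31 (SE 0.08) and 0.25 (SE 0.06). Endoplasmic reticulum stress genes rose by 0.22 (16 of 21 higher, adjusted p 0.017, adjusted p = 0.46 with an estimated correlation), with the chaperones DNAJB11 at 1.70 (SE 0.66) and CALR at 0.74 (SE 0.30). mRNAs with upstream reading frame or iron or polyamine control fell by 0.34 (9 of 16 lower, adjusted p 0.038, adjusted p = 0.31 with an estimated correlation). In that list the polyamine enzymes SRM, ODC1 and AMD1 read -2.27 (SE 1.01), -1.70 (SE 0.48) and -0.98 (SE 0.21), and the iron regulatory ACO1 1.08 (SE 0.57), with 1 lower adjusted over the list alone. Megakaryocyte and platelet genes did not pass (0.15, 26 of 38 higher, adjusted p 0.09), and neither did translation factors (0.00) or ATXN2 partners (-0.03). Adjusted over the list alone, translation factors and heat shock genes had 1 lower each, ATXN2 partners 1 higher, and autophagy, lysosome and mTOR genes 1 higher and 1 lower.

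Lists were tested without single arrays at the preset correlation only. In those tests noncoding RNAs and the proteasome kept their calls in control cells without any single array. The noncoding median was -0.63 without control subpolysomal P1 and -0.32 without P3. Without control subpolysomal P1 calls ended for oxidative phosphorylation (-0.00038), endoplasmic reticulum stress (0.36), erythroid genes (0.10), G2 and M phase (0.32) and upstream reading frame mRNAs (-0.27), and ribosomal proteins stood at -1.14 and S phase genes at 0.46. Without control subpolysomal P3 they ended for ribosomal proteins (-0.12), endoplasmic reticulum stress (0.36), S phase (0.17) and upstream reading frame mRNAs (-0.68), and oxidative phosphorylation stood at 0.90. Without control polysomal P2 they ended for ribosomal proteins (0.04), erythroid genes (0.12), G2 and M phase (0.14), S phase (0.11) and upstream reading frame mRNAs (-0.04). Without control polysomal P4 the endoplasmic reticulum stress call ended (0.11) and ribosomal proteins stood at -0.67. Without control polysomal P5 calls ended for oxidative phosphorylation (0.23), endoplasmic reticulum stress (0.22), erythroid genes (0.10), S phase (0.32) and upstream reading frame mRNAs (-0.55), and ribosomal proteins stood at -0.72. The 34 probes became 1, 1, 2, 4 and 1 without control arrays P1, P3, P2, P4 and P5, and 11, 11, 2, 12 and 2 without knockdown arrays P1, P3, P2, P4 and P5.

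**Figure D3:**
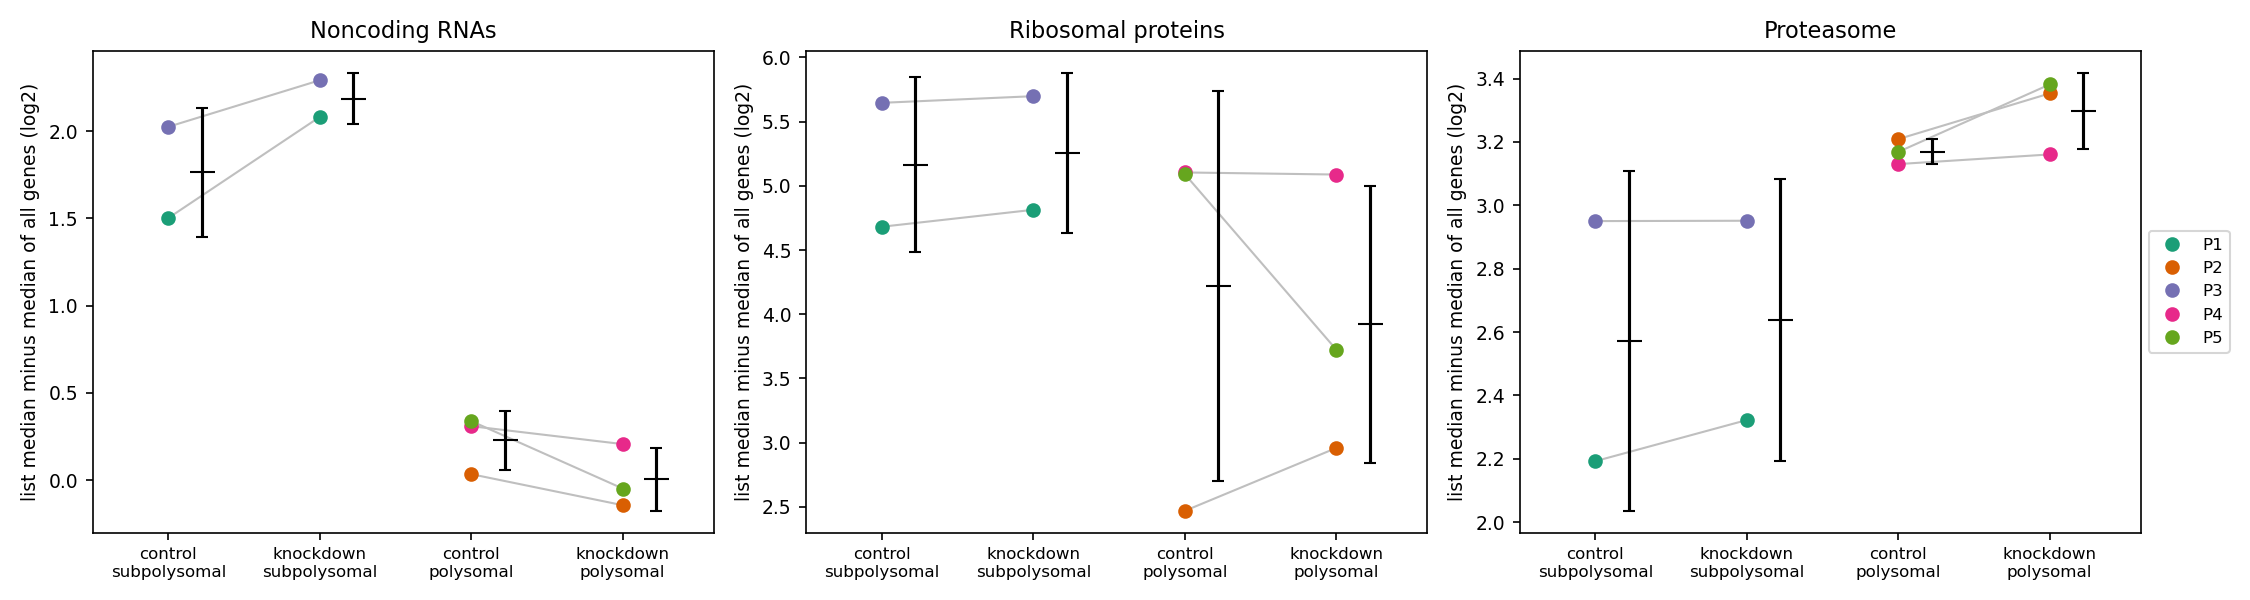
Median of a gene list minus the median of all genes (vertical axis, log2) for each array in the 4 groups, for noncoding RNAs, ribosomal proteins and the proteasome, where points are arrays coloured by P number, grey lines join arrays of the same number and black bars give mean and SD. Polysomal against subpolysomal RNA of control cells differed by a median of -1.15, -0.37 and 0.70 for the 3 lists.

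In ATXN2 knockdown cells polysomal and subpolysomal RNA (n = 3 against 2) differed most firmly in noncoding RNAs. Noncoding RNAs fell by a median of 0.78 (20 of 21 lower, adjusted p 5.9e-13, adjusted p = 0.0038 with an estimated correlation), and by 1.34 with median centring and 1.36 with the authors' values. Proteasome mRNAs rose by 0.88 (25 of 27 higher, adjusted p 6.9e-06, adjusted p = 0.048 with an estimated correlation), a call that ended with median centring (0.37, adjusted p 0.10) and with the authors' values (0.35, adjusted p 0.055). Ribosomal protein mRNAs fell by 0.86 (59 of 68 lower, adjusted p 1.9e-08, adjusted p = 0.34 with an estimated correlation), and by 1.55 with median centring and 1.57 with the authors' values (68 of 68 lower in both). limma called 43 probes, 7 higher and 36 lower, of which 20 have no gene name, and 31 with the replicate block. As in control cells the p-values can be too small, and the pools hold different P numbers. No probe was called with only the arrays compared or with a trended and robust prior. Of the 43, 25 were also called in control cells, all in the same direction, where 0.0545 would be expected of independent lists. The lists are not independent, because the arrays share P numbers, and the same holds for the correlation of 0.794 between the differences over 10522 probes.

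Genes higher in polysomal RNA of knockdown cells were LRP5 at 1.23 (SE 0.12), the malate dehydrogenase MDH1 at 1.23 (SE 0.13), DCAF7 at 1.11 (SE 0.11), SRRT at 1.09 (SE 0.06), CCDC32 at 0.87 (SE 0.09) and the RNA demethylase FTO at 0.35 (SE 0.04). Adjusted p ran from 0.00376 for SRRT to 0.0481 for FTO. The mitochondrial malate dehydrogenase MDH2 was higher as well, at 0.98 (SE 0.07, adjusted p 0.0129), but read -0.15 with median centring and -0.17 with the authors' values (adjusted p 0.974 each). Lower in polysomal RNA were RNU6-1 at -2.16 (SE 0.16), OIP5-AS1 at -2.13 (SE 0.21), IDS at -1.96 (SE 0.22), TLE5 at -1.78 (SE 0.20), FAAP20 at -1.76 (SE 0.12), NTAN1 at -1.68 (SE 0.16), RPS4X at -1.43 (SE 0.17), SLC27A5 at -1.28 (SE 0.14), RNF11 at -1.23 (SE 0.15) and FAM219B at -0.89 (SE 0.10). Adjusted p for these ran from 0.0122 for FAAP20 to 0.0481 for RNF11. RPS4X, a ribosomal protein, read -1.25 (SE 0.17, adjusted p 0.0877) in control cells, so a gene called with only a single hairpin need not differ between hairpins. RPS29 was again called on 1 of 4 probes (-3.06, the others -1.07 to -1.48) and CNOT7 on 1 of 3 probes (-1.27).

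Among noncoding RNAs of knockdown cells SNHG5 read -2.81 (SE 0.56), EPB41L4A-AS1 -2.80 (SE 0.38) and SNHG12 -0.47, with 9 of 21 lower adjusted over the list alone. Ribosomal proteins RPL12, RPL13 and RPL13A read -2.74 (SE 0.62), -1.86 (SE 0.38) and -1.51 (SE 0.31), with 5 lower adjusted over the list alone. The proteasome subunits PSMB6, PSMD2, PSMB1 and PSMA6 read 1.68 (SE 0.29), 1.50 (SE 0.36), 1.27 (SE 0.33) and 1.06 (SE 0.19), with 4 higher adjusted over the list alone. Endoplasmic reticulum stress genes rose by 0.45 (19 of 21 higher, adjusted p 0.0017, adjusted p = 0.38 with an estimated correlation), with MANF at 1.07 (SE 0.45), the stress sensor ATF6 at 0.88 (SE 0.26) and CALR at 0.65 (SE 0.30). S phase genes rose by 0.41 (29 of 31 higher, adjusted p 0.0042, adjusted p = 0.63 with an estimated correlation), with FEN1 at 1.75 (SE 0.73) and the replicative helicase subunits MCM6 and MCM7 at 1.74 (SE 0.71) and 1.09 (SE 0.42). Histone mRNAs fell by 0.11 (23 of 29 lower, adjusted p 0.0008, adjusted p = 0.63 with an estimated correlation), with H3C7 at -0.73 (SE 0.41) and H2BC21 at -0.37 (SE 0.11). Autophagy, lysosome and mTOR genes rose by 0.30 (20 of 29 higher, adjusted p 0.0499, adjusted p = 0.26 with an estimated correlation), with the protease CTSL at 2.16 (SE 0.51), the autophagy kinase ULK1 at 0.82 (SE 0.24), ATG7 at 0.39 and RPTOR at 0.35. Adjusted over the list alone, ATXN2 partners, erythroid genes and oxidative phosphorylation had 1 higher each, and lymphoid markers and heat shock genes 1 lower each. Oxidative phosphorylation (0.14), erythroid genes (0.07), G2 and M phase genes (0.26) and megakaryocyte genes (0.15) did not pass.

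Without knockdown subpolysomal P3 the calls of histones (0.01) and S phase genes (0.13) ended and ribosomal proteins stood at -0.21. Without knockdown subpolysomal P1 the autophagy call ended (0.18) and histones stood at -0.20. Without knockdown polysomal P2 no call ended, and noncoding RNAs stood at -1.17, the proteasome at 0.54, ribosomal proteins at -0.33, endoplasmic reticulum stress at 0.28 and S phase genes at 0.23. Without knockdown polysomal P4 the autophagy call ended (0.27) and ribosomal proteins stood at -1.35, and without control subpolysomal P1 or P3 the autophagy call ended at 0.30. The 43 probes became 4, 1, 8, 10 and 3 without knockdown arrays P1, P3, P2, P4 and P5, and 18 and 24 without control polysomal P4 and P5.

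The polysomal to subpolysomal ratio changed with ATXN2 knockdown for 5 lists at the preset correlation, for none with an estimated one, and for no single gene. Ribosomal protein mRNAs moved by a median of -0.25 (51 of 68 lower, adjusted p 0.0061), oxidative phosphorylation by -0.29 (48 of 70 lower, adjusted p 0.0286), erythroid genes by -0.12 (17 of 22 lower, adjusted p 0.0269) and histones by -0.13 (26 of 29 lower, adjusted p 8.03e-05). ATF4 targets moved by 0.53 (26 of 28 higher, adjusted p 0.0269). With an estimated correlation none passed (adjusted p = 0.895 with an estimated correlation for ATF4 targets and 0.817 for each of the others). limma called 0 probes, with 313 at an unadjusted p under 0.05, and 0 with 976 under the replicate block. The replicate block ended the calls of erythroid genes (adjusted p 0.054) and ATF4 targets (0.095) and added noncoding RNAs (-0.11, adjusted p 0.0012) and translation factors (0.23, adjusted p 0.0498), each with adjusted p = 0.731 with an estimated correlation in that fit. With median centring and with the authors' values the medians were -0.96 and -0.97 for ribosomal proteins, -0.81 and -0.82 for oxidative phosphorylation, -0.49 and -0.51 for erythroid genes, and 0.21 (adjusted p 0.0862, no longer passing) and 0.19 for ATF4 targets.

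Members of these lists had wide errors, with RPL12 at -1.35 (SE 0.88), RPS27 at -1.44 (SE 0.97), RPS12 at -0.95 (SE 0.61) and RPL11 at -0.28 (SE 0.12). HBE1 read -1.14 (SE 0.85), the carbonic anhydrase CA1 -0.73 (SE 0.53), HBD -0.50 (SE 0.44), NDUFC1 -0.38 (SE 0.27), NDUFA10 0.37 (SE 0.24) and the linker histone H1-2 -1.09 (SE 0.85). NDUFA10 took the other sign with median centring and with the authors' values, at lowest -0.13. WARS1 read 1.79 (SE 1.02), and SLC3A2 and SLC7A5, which join to form an amino acid transporter, 1.17 (SE 0.97) and 1.00 (SE 0.89), with SLC7A5 at -0.08 without the P1 and P2 arrays. The single genes with the smallest p, none passing, were PFKP at 0.91 (SE 0.21), DCAF7 at 0.67 (SE 0.15), MDH2 at 0.42 (SE 0.10, but -0.59 with median centring and -0.61 with the authors' values), SRRT at 0.33 (SE 0.08) and PLVAP at 0.28 on the higher side, and RNU6-1 at -1.06 (SE 0.22), BMP10 at -0.29, RPH3A at -0.26, CSNK1A1L at -0.21 and HLA-DQB1 at -0.20 on the lower. ATXN2 itself read -0.44 (SE 0.60).

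Every call of a ratio change depended on several arrays. Without control subpolysomal P1 calls ended for ribosomal proteins (0.07), erythroid genes (-0.07), oxidative phosphorylation (0.03) and histones (0.01). Without control subpolysomal P3 the ATF4 call ended (0.06), with ribosomal proteins at -0.43, oxidative phosphorylation at -0.66 and histones at -0.20. Without knockdown subpolysomal P1 calls ended for ATF4 targets (0.16) and erythroid genes (-0.06), with oxidative phosphorylation at -0.73 and histones at -0.30, and without knockdown subpolysomal P3 for ribosomal proteins (0.06), oxidative phosphorylation (0.09) and histones (0.05). Without control polysomal P2 calls ended for ATF4 targets (0.20) and erythroid genes (-0.03), with ribosomal proteins at -0.62. Without control polysomal P4 the ribosomal call ended (-0.16), with ATF4 targets at 0.85, erythroid genes at -0.20 and histones at -0.22. Without control polysomal P5 calls ended for ribosomal proteins (-0.11), ATF4 targets (0.13), erythroid genes (-0.07), oxidative phosphorylation (-0.19) and histones (-0.09). Without knockdown polysomal P2 they ended for ribosomal proteins (-0.05), ATF4 targets (0.06), erythroid genes (-0.09) and oxidative phosphorylation (-0.09), and without knockdown polysomal P4 for ATF4 targets (0.45) and erythroid genes (-0.05), with ribosomal proteins at -0.44 and oxidative phosphorylation at -0.51. Without knockdown polysomal P5 ATF4 targets stood at 0.87, erythroid genes at -0.20 and histones at -0.21. Without knockdown polysomal P4, limma called 1 probe.

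Signal that depends on the probe within a gene moved with the P numbers. On the probe-difference axis the P1 arrays stood at -10.7 (control) and -12.5 (knockdown), P3 at 17.1 and 17.9, P2 at -16.5 and -18.0, and P4 at 12.04 and 13.6. Pair P5 was split, with control at 7.85 and knockdown at -10.8. The main direction of all gene levels, 52.1% of their variance, put the P1 and P2 arrays and knockdown P5 apart from the rest as well, so the axis cannot be separated from gene levels on these arrays. For ACTB the difference between probes ran from -5.61 to 0.38 log2 units between arrays. Each group held arrays from both ends of this axis.

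**Figure D4:**
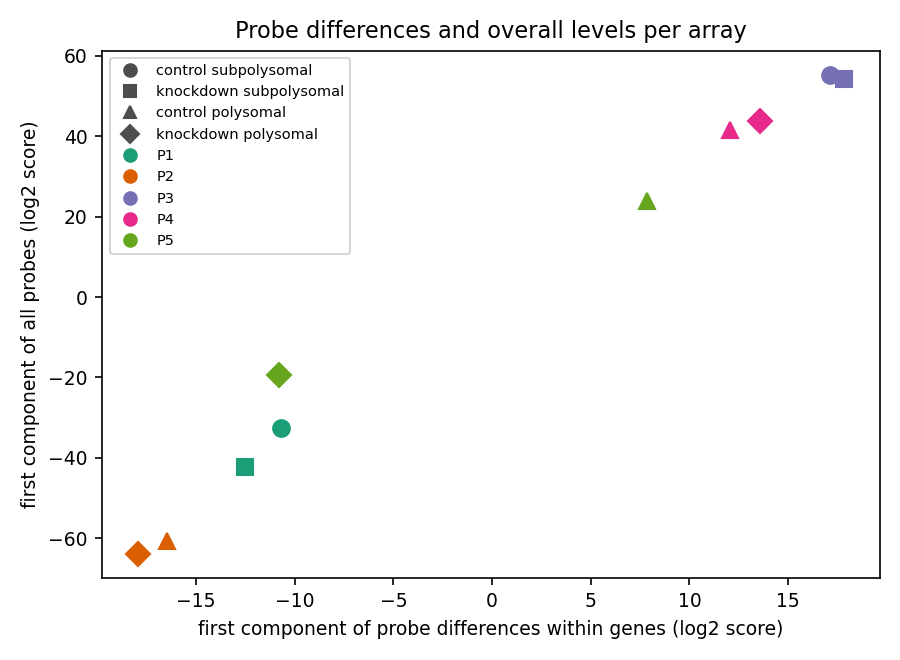
First component of the difference between probes of the same gene (horizontal axis, arbitrary units) against the first component of all probe levels (vertical axis, arbitrary units) for the 10 arrays, where shapes give the group and colours the P number. P5 is the only pair far apart, at 7.85 for control and -10.8 for knockdown.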

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

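For 5 gene lists the shift with ATXN2 knockdown differed between polysomal and subpolysomal RNA at the preset correlation only. With an estimated correlation the adjusted p was 0.895 for ATF4 targets and 0.817 for the others, and the replicate block ended the calls of erythroid genes and ATF4 targets. Each is given here because a difference between RNA pools can also come from arrays of unequal quality. Ribosomal protein mRNAs stood apart by -0.25, with a median shift of -0.26 in polysomal and 0.03 in subpolysomal RNA. Oxidative phosphorylation mRNAs stood apart by -0.29 (-0.20 and 0.07), erythroid genes by -0.12 (-0.02 and 0.08) and histones by -0.13 (-0.12 and 0.05). ATF4 targets stood apart by 0.53 (0.39 and -0.06).

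No test of the first pattern, deviations shared by arrays of the same P number, was chosen after the result was seen. RNA loss that strikes probes of a gene unequally predicts a low correlation between the loadings of 2 probes of a gene on this deviation, and different gene levels in each experiment predict a high one. The correlation was 0.594 (95% bootstrap interval 0.527 to 0.657), with 30.4% of genes having probes of opposite sign. The interval resamples the 694 genes on the same arrays, so it does not measure the spread between arrays or experiments. Probe-specific loss and gene levels cannot be told apart, because the value lies between the limits of 0.5 and 0.8 set for them, and both may act together. The same 2 probes correlated at 0.856 in their polysomal to subpolysomal difference over all arrays. That is a different measure from the loadings, and both correlations were not compared by a test. Single called genes differed between probes, such as RPS29 in control cells (-2.38 on 1 probe, -0.19 to -0.38 on the others).

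All tests of the second pattern, the lists shifted in polysomal RNA with knockdown, were chosen only after the result was seen, apart from the counts of lists over splits of the arrays. With the probe-difference axis and the replicate block in the model ATF4 targets kept 0.38. That fit could hardly remove their shift, because the axis acts mainly through P5 while the shift lies in P2. The axis differed by -18.6 in P5, where the list stood at -0.05, and by -1.46 in P2, where it stood at 1.76. So an effect of this axis that is equal in every pair does not explain the rise in P2. Oxidative phosphorylation stood at -0.040 in the same fit. This leaves unequal RNA quality open, because the axis acts mainly through P5 and pairs P2 and P4 differ in sign (-0.44 and 0.22). The axis does not cover other faults of the control array of P2 (highest intensity 140375, low ACTB on all probes), which stay open. The ATF4 targets stood at -0.085 in pairs P4 and P5 together, which restates the pair values and does not say why P2 differs. An effect of the hairpin in every experiment stays open, since only 2 of 6 lists, translation factors and histones, kept their direction in each pair, but 3 pairs cannot part a small effect from their spread.

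The tests of chance by relabelled arrays were, for the probe counts, chosen only after the result was seen. The real grouping gave 0 probes, a count that all 10 splits of the polysomal arrays (highest other 0, with the subpolysomal arrays as labelled) and all 60 splits over both pools reach by construction, so the probe counts decide nothing about chance. The 6 lists of polysomal RNA were reached by 6 of 10 splits (highest other 10), where 10 splits are too few for a share under 0.05, and the 2 averaged lists by 53 of 60 (highest other 9), consistent with chance. The split with most probes, 6560 averaged and 3117 in polysomal RNA, sets the P1 and P2 arrays and knockdown P5 against the rest, which points to structure of the samples along the probe-difference axis. Among splits that part every pair, the real one included, 2 of 4 reached the 6 lists in polysomal RNA (highest other 7) and 13 of 16 the 2 averaged lists (highest other 6), and no other such split called a probe.

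No test of the third pattern, noncoding RNAs and ribosomal protein mRNAs lower in polysomal RNA, was chosen after the result was seen. Long noncoding RNAs outside the list stood at -0.030 in control cells (264 of 392 lower), and whether the shift belongs to noncoding transcripts as a class cannot be told apart from a property of the listed genes, because their adjusted p with an estimated correlation was 0.0646 in control and 0.0231 in knockdown cells. Other mRNAs with a 5' terminal oligopyrimidine tract, the leader that ties ribosomal protein mRNAs to mTOR signalling, stood at -0.79 (15 of 18 lower), consistent with a property of the tract. High signal does not explain it, since of 10000 random lists matched on signal 0 had a median as low as these mRNAs (random median 0.21) or as the ribosomal proteins (0.28). The proteasome lay at the 99.98th percentile of its matched lists (random median 0.20).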

How the results depend on the processing

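Limits are the small number of arrays (2 or 3 per group), P numbers along which signals of probes of the same gene part, unknown upstream processing, 1 platform and 1 hairpin against ATXN2. Signal over background limits the size of changes, since signals near the floor compress differences. The cause of the moves below was not tested. Background correction with normexp, the uncorrected scanner signals and the slide as a block were named beforehand but not run, as the values were processed already and no slide is given, and a fixed replicate block cannot be fitted for polysomal against subpolysomal RNA.

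Counts of called probes, 34 in control and 43 in knockdown cells for polysomal against subpolysomal RNA, depended on the settings. They were 22 and 24 with the authors' values, 2 and 23 with probes above background on all arrays, 0 and 0 with only the arrays compared, 0 and 0 with a trended and robust prior, and 21 and 30 for an absolute log2 difference of at least 1. In control cells the count was 17 without a filter and 15 with a random replicate block, and in knockdown cells 22 with median centring. Settings chosen after seeing the data gave 1 and 14 with the background mode subtracted, 183 and 469 with the probe-difference axis as covariate, 0 and 0 without P1 and P2, and 3 and 5 without P5. Leaving out single arrays gave 1 to 12 in control and 1 to 42 in knockdown cells, and 0 to 1 for the change of the ratio. For knockdown against control the count was 0 in every setting.

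Counts of shifted lists moved as well. In polysomal RNA with knockdown the 6 lists became 3 without P1 and P2, 0 with an estimated correlation, 0 by fry and 2 to 9 without single arrays. In subpolysomal RNA the 0 became 5 with median centring, 3 with the authors' values, 1 with the fixed replicate block, 1 with the probe-difference axis, 2 with both, 8 without P1 and P2, and 0 to 4 without single arrays. Averaged, the 2 became 1 with quantile normalization within each fraction, median centring, cyclic loess, the authors' values or the background mode subtracted, 4 with the replicate block, 6 with the probe-difference axis, 5 without P1 and P2, 4 without P5, 0 with an estimated correlation, 0 by fry and 2 to 4 without single arrays. For polysomal against subpolysomal RNA the 9 lists of control cells became 5 without P1 and P2, 4 without P5, 2 with an estimated correlation, 3 by fry and 4 to 10 without single arrays. The 7 of knockdown cells became 11 with the probe-difference axis, 2 with an estimated correlation, 3 by fry and 6 to 10 without single arrays. The 5 for the change of the ratio became 3 without P5, 0 with an estimated correlation, 0 by fry and 0 to 6 without single arrays.

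Median centring and the authors' values, both without the quantile step, moved several list medians widely, as given beside them. Without the P1 and P2 arrays ATF4 targets lay in the lower direction in polysomal RNA with knockdown (-0.088). The proteasome call in knockdown cells ended with median centring (0.37, adjusted p 0.10) and with the authors' values (0.35, adjusted p 0.055). The correlation of the knockdown differences between the pools ran from -0.489 to 0.378 without single arrays. Among named genes that did not pass, ATP5PB in polysomal RNA with knockdown and NDUFA10 and MDH2 in the change of the ratio took the other sign with median centring and with the authors' values. MDH2 in knockdown cells, 0.98 polysomal against subpolysomal, reversed to -0.15 with median centring and -0.17 with the authors' values. Of the other settings of counts, correlations and the ATXN2 level 297 stayed the same and 87 moved. For named genes 4033 stayed the same, 461 weakened, 17 strengthened, 9 moved and 2 reversed. For a gene that did not pass, the same means not passing again, and for a passing gene, weakened means that its call was lost. Each of the 13 control and 16 of 17 knockdown genes named as passing kept its direction in all settings, and none passed in every setting.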

Other observations

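Fitting the mean of both hairpins with the replicate block as a random effect, a fit chosen after seeing the data, called 51 probes for polysomal against subpolysomal RNA, 9 higher and 42 lower. It added the actin bundler FSCN1 at 1.31 (SE 0.15), the proteasome subunit PSMB6 at 1.77 (SE 0.21), the ATP synthase subunit ATP5F1B at 1.07 (SE 0.13), the disulfide oxidase QSOX1 at 0.95 (SE 0.12) and the cleavage factor CPSF1 at 0.49 (SE 0.06) on the higher side. Lower were C8orf88 at -1.55 (SE 0.17), the box C/D small nucleolar RNAs SNORD104 at -1.33 (SE 0.17) and SNORD84, not above background on any polysomal array, by at least 1.41-fold, FAM89B at -1.23 (SE 0.15), SLC27A5 at -1.12, ADA at -0.80 (SE 0.09), TMEM42 at -0.63, U2AF1L4 at -0.54 and RNPEPL1 at -0.39. The count was 309 (73 higher, 236 lower) with no block, 1560 (548 higher, 1012 lower) with the probe-difference axis as covariate, 116, 20, 31, 6 and 4 without the arrays of P1 to P5, and 1 when each pair was averaged first.

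Among classes of transcripts outside the lists, small nucleolar RNAs fell slightly. They stood at -0.11 in control and -0.11 in knockdown cells, 115 of 134 lower in each (adjusted p = 0.00866 with an estimated correlation in control and 0.00484 in knockdown cells). Small nuclear RNAs stood at -0.84 and -0.96 (10 and 11 of 11 lower, adjusted p = 0.184 and 0.0711 with an estimated correlation), which did not pass. Pseudogenes stood at -0.01 and -0.02 (175 and 192 of 316 lower, adjusted p = 0.0768 and 0.00732 with an estimated correlation). Of mRNAs known for a 5' terminal oligopyrimidine tract, PABPC1, the poly(A)-binding partner of ATXN2, read -1.77 in both, EEF1G -1.70 in control and -1.49 in knockdown cells, EIF3F -1.17 and -1.45, EIF3H -1.33 and -0.90, EEF2 -1.60 and -0.53, EEF1A1 -1.14 and -0.30, and VIM -0.88 and -0.61. TPT1 (0.13 and 0.06) and EIF3A (0.42 and 0.26) read the other way. The 18 mRNAs stood at -0.79 in control and -0.71 in knockdown cells (adjusted p = 0.013 and 0.0076 with an estimated correlation), 13 of them are members of the translation factor list, and their polysomal to subpolysomal ratio differed between hairpins by -0.03 (p = 0.541 with an estimated correlation). Both depended on the scaling: the medians were -0.90 and -1.57 with median centring, -1.04 and -0.85 with cyclic loess and -0.91 and -1.59 with the authors' values, and the difference -0.43, -0.14 and -0.44.

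Hypothesis 1: in these cells mRNAs with a 5' terminal oligopyrimidine tract may lie outside polysomes to a larger part than other mRNAs. It rests on the median of -0.79 in control cells and the low share of 0 in 10000 matched lists. Both are relative to other genes, since the arrays were scaled to the same distribution, and neither gives the part of an mRNA outside polysomes. The matched lists draw other genes on the same arrays, so their share does not measure the spread between arrays. Ribosomal proteins had the same share in control cells, but stood at 0.04 without control polysomal P2. Leaving out single arrays was not tried for the 18 other mRNAs. Whether ATXN2 loss alters the place of the mRNAs with the tract is left open by the scalings. Blotting or quantitative PCR of PABPC1, EEF1G and RPL13 across single gradient fractions, with and without an mTOR inhibitor, would test it.

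Hypothesis 2: the rise of ATF4 targets in polysomal RNA could come from single arrays or cell samples of pair P2. Relative to all genes the list was lowest of all 10 arrays on control P2 (0.89) and highest on knockdown P2 (3.22). Measuring WARS1, ASNS and SLC7A5 in total RNA of further transductions with a second hairpin, beside phosphorylated eIF2 alpha, would test it.

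Hypothesis 3: loss of ATXN2 may lower cholesterol synthesis mRNAs in both pools and so act on their level and not on their translation. However, the averaged call of 2 lists was reached by 53 of 60 relabellings. The pairs were also divided in each pool. The list was lower in subpolysomal P3 and in polysomal P2 and P4, but slightly higher in subpolysomal P1 (0.07) and polysomal P5 (0.08). HMGCS1, INSIG1 and IDI1 in total RNA of at least as many independent knockdowns as here, with sterol-depleted and sterol-fed controls, would test the hypothesis.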
